A study of Mus musculus with 8 samples.

How the data were processed

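RNA from isolated mouse Kupffer cells was profiled in 5 naive and 3 CCl4 libraries. Per the labels' protocols, 1.5 ug of total RNA entered a directional library preparation. The submitters' processing notes name kallisto 0.42.4 and the genome build GRCm38. The deposited values are TPM per RefSeq transcript, per the file headers, and each library sums to between 999999 and 1000001. The index, read trimming and the isolation or sorting of the cells are not given in the sources used here. TPM keep no depth, so no counting precision could be attached to a value, and precision was taken from the spread between libraries.

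The files list 107384 transcripts. A RefSeq gene table of GRCm38.p6, the same build as the authors', gave a gene for 86722 of them by accession without version, 46184 of which matched with the version too. The 20662 unmatched transcripts held 6.06% to 7.58% of the TPM in a library and were left out, so the sum of some genes is incomplete. Transcripts were summed to 32903 genes. Each RefSeq coordinate given is on GRCm38. The 7SL RNA genes Rn7s1 and Rn7s2 held 27.5% to 41.3% of all TPM and Rn7sk 3.45% to 6.05%, while protein-coding genes held 45.5% to 56.0%. No mitochondrially encoded gene had a matched transcript. A fold change therefore depends on how this noncoding share is treated, which the rescaling alternatives address.

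Genes with at least 1 TPM in at least 3 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Gene lists were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 49 lists with at least 3 tested members (24 on Kupffer cell biology, 14 on other cell types, 11 gene families). The same test with an estimated correlation called 0 lists with TPM as deposited, so no camera call held there, and fry, which tests whether a list's genes move on balance one way, called 19. Summed TPM of lists were compared by an exact two-sided permutation test over the 56 splits.

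Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The exact permutation test of summed TPM was an exception, since the plan named the sums without a test. The rule took the 10 largest rises and falls with an adjusted p under 0.05, a mean of at least 10 TPM and no overlap between groups, up to 4 members of each Kupffer cell list by adjusted p, 18 preset Kupffer cell and macrophage genes, and the 2 most abundant members of each other cell type list. Some genes this rule took are not reported here. Other members of these lists that the text names were chosen after their values were seen. Alternatives were other pseudocounts, filters, scalings, variance settings, library weights, a replicate block, transcript-level tests, protein-coding genes alone and leaving out each library. A pair of further rescalings, and the estimated correlation under the other settings, were chosen after seeing the data.

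The fit was tested on simulated data for this comparison, in 20 draws of 200 changed genes with 15097 to 15153 genes in the fit. On average it recovered 85.3% of genes raised 4-fold (71.4% to 93.9% over the draws), 43.7% of genes raised 2-fold (34.7% to 52.0%), 41.5% of genes lowered to 0.5 of their level (23.4% to 61.2%) and 78.8% of genes lowered to 0.25 of it (64.4% to 93.6%). It called 1 to 12 unchanged genes per draw. The simulated genes varied independently, and 200 changed genes are far fewer than the 5906 called in the data. The cutoff set by Benjamini-Hochberg adjustment depends on how many genes change, so these rates need not hold for the real comparison. Any pair of libraries shared an identical TPM above 0 in at most 1 of the 15629 tested genes. The male-specific gene Ddx3y was present and Xist was at most 0.181 TPM in all 8 libraries.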

Results

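Bulk RNA-seq was used to measure gene expression in Kupffer cells, the resident macrophages of the liver, from wild-type mice. The 8 libraries fell into 2 groups. The 5 naive libraries came from untreated mice. The 3 CCl4 libraries came from mice given carbon tetrachloride, a hepatotoxin metabolised by hepatocytes to a reactive radical, at 0.75 mL/kg 3 times a week for 8 weeks, which scars the liver. The labels number the CCl4 libraries 1, 2-4 and 3, and they do not say whether 2-4 stands for a pool of mice. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these libraries, part of which may be technical. Values were in TPM, a transcript abundance scaled to the library's total, which keeps no sequencing depth, so the depth behind each value is unknown. Between 14059 and 15063 genes reached 1 TPM in a library. The comparison asked how the transcriptome of Kupffer cells differed between fibrotic and naive livers.

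In the CCl4 libraries 24 of 25 genes that mark resident Kupffer cells were lower by limma, and 10 of 16 monocyte genes, 13 of 14 genes of MHC class II antigen presentation and 11 of 20 genes of scar-associated macrophages were higher. As lists these were called by camera with a preset correlation, and with an estimated correlation their adjusted p was 0.64 for the first 3 and 0.742 for the scar-associated genes. Clec4f, a C-type lectin receptor restricted to Kupffer cells in the mouse, averaged 1397 ± 416 TPM (SD, n = 5) in naive and 77.7 ± 11.0 TPM (SD, n = 3) in CCl4 libraries. Ccr2, the chemokine receptor that guides monocytes out of the bone marrow, averaged 18.6 ± 11.1 TPM (SD, n = 5) and 251.1 ± 63.9 TPM (SD, n = 3). Markers of liver sinusoidal endothelium were lower too, with a median log2 fold change of -4.44 against -2.69 for the Kupffer cell genes. Of 15629 genes tested, limma called 5906 at an adjusted p under 0.05, 2393 higher and 3513 lower in CCl4. Of these, 3182 changed at least 2-fold, 1074 upward and 2108 downward. The groups did not overlap for 36.9% of the tested genes, where chance gives 3.57% for 5 against 3 libraries. With quantile normalization, 4011 genes were higher and 3086 lower, so the balance between rises and falls depended on the scaling, and with a pseudocount of 5 the count changed at least 2-fold was 1799.

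The first principal component held 71.9% of the variance and separated the groups. Naive libraries 1 to 4 correlated with each other at 0.968 to 0.981 (Pearson's r across genes, which are not independent replicates). Naive replicate 5 correlated with them at 0.943 to 0.951 and with the CCl4 libraries at 0.878 to 0.888, above the 0.813 to 0.846 of the other naive libraries. Without naive replicate 5, limma called 6738 genes.

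**Figure D1:**
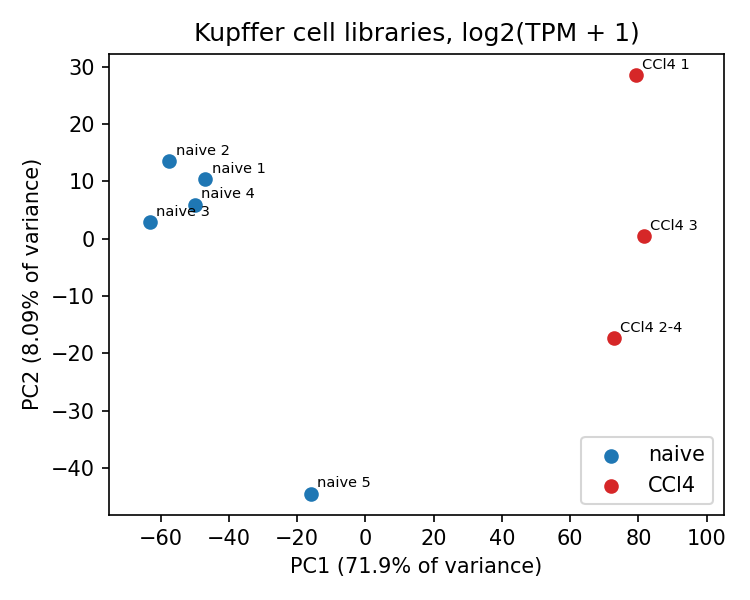
Principal components of log2(TPM + 1) over the tested genes, 1 point per library, with the first component on the horizontal axis (71.9% of the variance) and the second on the vertical axis (8.09%). The 3 CCl4 libraries lie between 72.8 and 81.5 on the first component, and naive replicate 5 lies at -16.0 and apart from the other naive libraries on the second.

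Of the 25 genes on the Kupffer cell identity list, 24 fell and none rose, with a median log2 fold change of -2.69 (24 lower adjusted over the list alone; camera adjusted p = 7.79e-14, and adjusted p = 0.64 with an estimated correlation). Clec4f (GRCm38 chromosome 6, 83644542 to 83656116) fell by 4.11 on the log2 scale (SE 0.241, adjusted p = 1.59e-06). Timd4 (chromosome 11, 46810786 to 46844333), the phosphatidylserine receptor that marks long-lived Kupffer cells, went from 110.7 ± 30.5 TPM to 3.75 ± 0.739 TPM, a log2 fold change of -4.52 (SE 0.225, adjusted p = 1.59e-06). Vsig4, a complement receptor that captures bacteria from blood, fell by 3.70 (SE 0.301), Folr2 by 3.62 (SE 0.327), Cd5l, a secreted scavenger receptor family protein, by 3.13 (SE 0.222) and Marco by 2.55 (SE 0.252). The transcription factors Nr1h3, which encodes the oxysterol receptor LXR alpha, and Spic fell by 1.08 (SE 0.189) and 1.38 (SE 0.285). Id3, a transcriptional regulator of Kupffer cell identity, stood at 490.3 ± 77.5 TPM in naive and 515.1 ± 107 TPM in CCl4 libraries, a difference within the spread (adjusted p = 0.813). Cdh5, an adhesion molecule of endothelium that is also on this list, fell by 4.00 (SE 0.221), and Fcna, which encodes a ficolin, by 4.12 (SE 0.217).

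Liver sinusoidal endothelium markers were measured as a check on other cells in the preparations. All 17 fell, with a median log2 fold change of -4.44 (17 lower adjusted over the list alone; camera adjusted p = 1.24e-14, and adjusted p = 0.64 with an estimated correlation). Clec4g, a lectin of sinusoidal endothelium, averaged 2289 ± 586 TPM in naive and 89.0 ± 42.2 TPM in CCl4 libraries. Aqp1, a water channel of endothelium, averaged 1605 ± 338 TPM and 100.9 ± 57.1 TPM. Their summed TPM was 12390 ± 2833 in naive and 706.3 ± 204 in CCl4 libraries, against 6966 ± 1648 and 1348 ± 167 for the Kupffer cell identity list (exact permutation p = 0.0357 for each, two-sided, the smallest that 5 against 3 libraries allow; 0.094 adjusted over the lists). The largest falls also included Gpr182, Ltbp4 and Cyp4b1, with log2 fold changes of -5.07, -5.06 and -5.15.

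Genes shared by macrophages went both ways. Adgre1, which encodes the F4/80 antigen, averaged 159.6 ± 48.7 TPM in naive and 149.9 ± 91.4 TPM in CCl4 libraries (adjusted p = 0.686). Csf1r was at 2.02 ± 1.91 TPM and 5.62 ± 3.05 TPM (adjusted p = 0.0645); its value rests on 1 matched transcript, and the unmatched transcripts leave open whether its sum is complete. On the macrophage core list 8 of 15 genes rose and 3 fell (9 and 3 adjusted over the list alone). Those that fell were Mrc1, the mannose receptor, which sinusoidal endothelium also expresses, with a log2 fold change of -2.73, and Maf and Mertk, at -1.81 and -1.37. Ly6c2, a gene of the monocyte list, was near the floor in both groups, at 1.65 ± 1.58 and 0.982 ± 1.70 TPM. It shares near-identical sequence with Ly6c1.

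**Figure D2:**
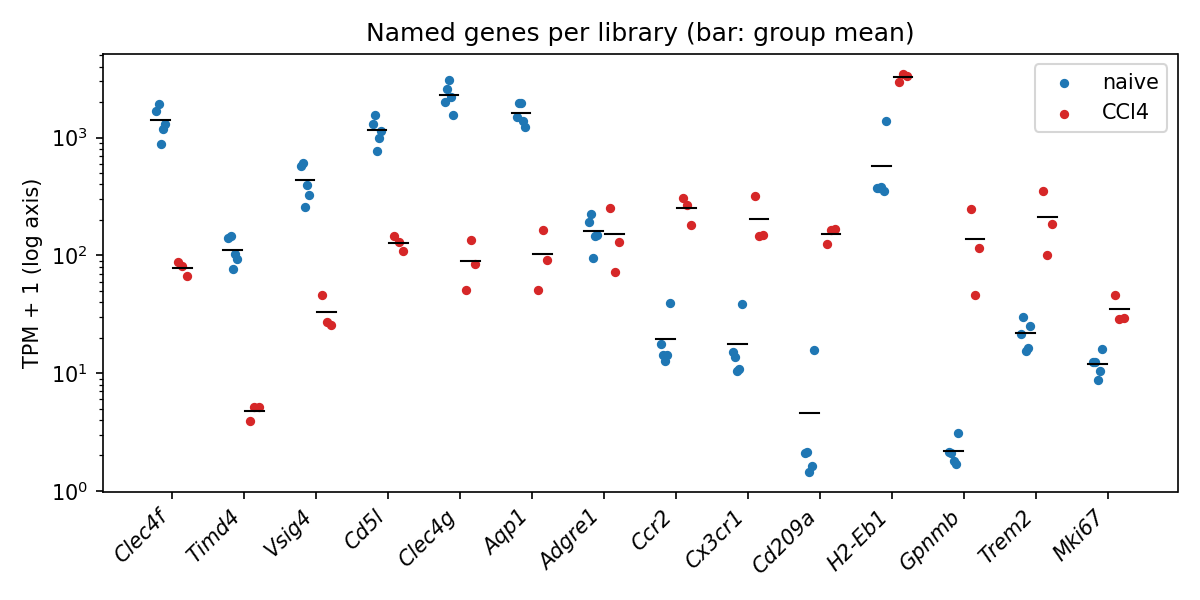
TPM + 1 of 14 named genes on a log axis, 1 point per library (5 naive, 3 CCl4), with a bar at each group mean. The Kupffer cell and endothelial genes on the left have lower values in every CCl4 library, and Adgre1 overlaps between the groups.

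Monocyte genes were higher: 10 of 16 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 5.01e-05, and adjusted p = 0.64 with an estimated correlation). Ccr2 rose by 3.79 (SE 0.341, adjusted p = 1.23e-05), S100a4 by 3.39 (SE 0.342) and Cx3cr1, the fractalkine receptor, by 3.62 (SE 0.416). The fall was Hp, haptoglobin, which hepatocytes also make, at -2.21. Cx3cr1 is also on the macrophage core list. Of the 18 monocyte genes listed, Chil3 and Vcan were below the filter, with at most 2.95 and 0.422 TPM in a library. Ly6c2, near the floor in both groups, was not called (adjusted p = 0.584 by limma). Among antigen presentation genes of MHC class II, 13 of 14 rose and none fell (13 adjusted over the list alone; camera adjusted p = 4.13e-07, and adjusted p = 0.64 with an estimated correlation). H2-Eb1, a class II beta chain, averaged 572.1 ± 457 TPM in naive and 3268 ± 256 TPM in CCl4 libraries, and Ciita, the class II transactivator, rose by 3.20 (SE 0.436). Naive replicate 5 held 1389 TPM of H2-Eb1, and the other naive libraries 349.8 to 377.2. It also held 68.7 TPM of Ciita against 14.5 to 16.9 in the other naive libraries, 38.2 TPM of Ccr2 against 11.6 to 16.8 and 37.3 TPM of Cx3cr1 against 9.45 to 14.2.

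The largest rises were in Cd209a, a lectin of monocyte-derived dendritic cells, and Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages. Cd209a (chromosome 8, 3743395 to 3748984) averaged 3.60 ± 6.19 TPM in naive and 151.8 ± 23.2 TPM in CCl4 libraries, a log2 fold change of 5.77 (SE 0.652, adjusted p = 5.73e-05). Naive replicate 5 held 14.7 TPM of it and the other naive libraries 0.444 to 1.15, and without naive replicate 5 the log2 fold change of Cd209a was 6.39. Gpnmb (chromosome 6, 49036518 to 49058182) averaged 1.16 ± 0.545 and 135.4 ± 102 TPM, a log2 fold change of 5.70 (SE 0.432, adjusted p = 4.12e-06), with 246.0 TPM in CCl4 replicate 1, 45.5 in 2-4 and 114.8 in 3. Also among the 10 largest rises were the lectins Mgl2 and Clec10a, at 3.84 and 3.77 (12.1 TPM of Mgl2 in naive replicate 5 and 2.13 to 4.10 in the other naive libraries), the chemokine receptor Cxcr4 at 4.22 (adjusted p = 0.233 in the transcript-level test), Ifnb1, the type I interferon, at 3.69 and Fcrls at 3.65. Dendritic cell genes went both ways: 4 of 14 rose, Cd209a and Flt3 among them, and 5 fell, Clec9a and Zbtb46 among them. Adjusted over the list alone these were 4 and 5, and the camera adjusted p was 0.758. The 2 most abundant members went opposite ways, Wdfy4 at 1.42 (adjusted p = 0.00294 by limma) and Dpp4 at -1.885. All 17 endothelial markers fell too, with a median log2 fold change of -4.44.

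Scar- and lipid-associated macrophage genes were higher on balance: 11 of 20 rose and 2 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.00592, and adjusted p = 0.742 with an estimated correlation). This call was lost with median-of-ratios rescaling (adjusted p = 0.0502) and quantile normalization (0.0814), and the median log2 fold change, 0.81, was 0.45 without CCl4 replicate 1. Trem2, a lipid-sensing receptor, rose from 20.7 ± 6.04 to 212.1 ± 129 TPM, Cd63, a tetraspanin of late endosomes, by 2.90 (SE 0.268) and Cd9 by 0.74 (SE 0.216; adjusted p = 0.0906 without CCl4 replicate 1). Spp1, osteopontin, did not pass the test at 30.5 ± 34.0 and 37.2 ± 19.5 TPM. Naive replicate 4 held 88.9 TPM of Spp1 and the other naive libraries 3.10 to 29.4. Its log2 fold change, 0.84, ranged from 0.28 to 1.39 without 1 library. The fatty acid handling genes Fabp4 and Cd36 fell, by 2.95 (SE 0.302) and 2.19 (SE 0.345). Both are also expressed by endothelium, whose sinusoidal markers fell with a median log2 fold change of -4.44. On the macrophage fusion list 10 of 21 genes rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.154). Trem2 rose there, and Cd81 and Itgb3, at -1.89 and -2.48, fell.

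More uptake receptor and complement genes fell than rose. Of the 25 Kupffer cell identity genes, 14 are also on other lists, Clec4f, Timd4, C6, Cd163 and Slc40a1 among them, so these lists overlap with that one. The endothelial markers also fell, all 17 with a median log2 fold change of -4.44. Of these, 1 is on the uptake list (Fcgr2b) and 1 on the apoptotic cell clearance list (Stab2). The uptake list also holds Mrc1 and Cd36, which endothelium expresses too and which fell by 2.73 and 2.19, so its endothelial part is not limited to the shared marker. Among uptake and capture receptors 16 of 25 fell and 6 rose (16 and 7 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.742 with an estimated correlation), with Clec1b at -3.58 and Scarf1 at -3.21. Across the naive libraries Scarf1 was highest in replicate 3 (97.0 TPM) and lowest in replicate 5 (52.4), as was the endothelial gene Clec4g (3090 and 1557). Clec1b was also lowest in replicate 5 (176.9), and Clec4f was lowest in replicate 3 (877.5). The source of Scarf1 and Clec1b was not tested. Of 16 complement genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00188, and adjusted p = 0.742 with an estimated correlation). C6, a component of the membrane attack complex, fell by 4.03 (SE 0.262) and C4b by 3.49 (SE 0.202). The summed TPM of complement genes was 5196 ± 1114 (SD, n = 5) in naive and 4405 ± 1713 (SD, n = 3) in CCl4 libraries, a difference within the spread (exact permutation p = 0.464, two-sided), with 6235 in CCl4 replicate 1. Among apoptotic cell clearance genes 9 of 17 fell and 6 rose (9 and 8 adjusted over the list alone; camera adjusted p = 0.468). By fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, this list was lower (adjusted p = 0.00241). Stab2, a scavenger receptor of sinusoidal endothelium, fell by 4.44 and Gas6 by 2.45. In iron and haem handling 7 of 20 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.202). The haemoglobin scavenger receptor Cd163 fell by 3.75 (SE 0.245) and the iron exporter Slc40a1 by 2.69 (SE 0.276). LXR target genes had 6 of 16 lower and 1, Arl4c, higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.338), and were lower by fry (adjusted p = 0.0147).

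Cell cycle genes rose in the CCl4 libraries, 18 of 30 with none lower (18 adjusted over the list alone; camera adjusted p = 2.2e-07, and adjusted p = 0.742 with an estimated correlation). Mki67, a proliferation marker, went from 11.0 ± 2.77 to 33.8 ± 9.97 TPM. Of 20 immediate early and dissociation stress genes 16 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.688 with an estimated correlation). Atf3 went from 60.6 ± 10.5 to 448.1 ± 152 TPM. Several of these genes respond to tissue dissociation. Lysosome genes rose in 12 of 28 cases and fell in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.893 with an estimated correlation). Their summed TPM did not pass at 8747 ± 1432 in naive and 12560 ± 4163 in CCl4 libraries (exact permutation p = 0.0714, two-sided). The camera call was lost without CCl4 replicate 1 (adjusted p = 0.167), with median-of-ratios rescaling (0.0509) and under quantile normalization (0.286). Cd63 rose by 2.90 and Ctsl, cathepsin L, fell by 2.84. Among naive libraries Ctsl was highest in replicate 3 (954.7 TPM) and lowest in replicate 5 (592.3 TPM), as was the endothelial gene Clec4g. This alone does not show an endothelial source of Ctsl, which was not tested.

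Inflammatory and matrix genes moved in both directions. Of 27 cytokine and chemokine genes 11 rose and 6 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.144), and fry called the list higher (adjusted p = 0.00084). Ccl4, a chemokine that shares letters with the toxin, went from 61.3 ± 3.97 to 240.1 ± 2.16 TPM, and Osm, oncostatin M, rose by 3.33 (SE 0.240), while Cxcl13 fell by 4.05 (SE 0.289). Of 26 type I interferon response genes 4 rose and 7 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.906), with Mx1 at 1.32 and Ifi44 at -1.85. Interferon gamma response genes fell in 9 of 19 cases and rose in 2 (9 and 3 adjusted over the list alone). The camera adjusted p was 0.0929, and 0.00391 by fry, and Cxcl9 fell by 2.75 (SE 0.185). Among naive libraries Cxcl9 was lowest in replicate 5 (22.6 TPM), as was the endothelial gene Clec4g, and the others were close together (33.5 to 36.3 TPM). Iigp1, Gbp4 and Socs1, which also fell, were highest in replicate 3 and lowest in replicate 5, as was Clec4g. Naive replicate 5 was the naive library nearest to the CCl4 libraries on the first component (-16.0). A low value there need not mean an endothelial source, and the source of these transcripts was not tested. Matrix remodelling and profibrotic factors rose in 10 of 25 cases and fell in 4 (10 and 6 adjusted over the list alone; camera adjusted p = 0.0716), with Tgfbi at 2.49, Pdgfb at 1.60, Timp3 at -3.71 and Sparc at -2.85. The endothelial markers fell beside them, with a median of -4.44. Sparc, like the endothelial gene Clec4g, was highest among naive libraries in replicate 3 (738.9 TPM) and lowest in replicate 5 (337.6 TPM). The source of Sparc was not tested. Alternative activation genes had 3 of 15 higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.858).

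Several lists that camera did not call in the primary test were called in other settings. Among these settings, the replicate block in effect compared only replicates 1 and 3 of each group. The adjusted p of the macrophage core list was 0.0429 with no filter, 0.035 with library weights, 0.0462 with protein-coding genes only, 0.0408 rescaled to them, 0.000736 with the replicate block, 0.00727 without CCl4 replicate 2-4, and 0.0462, 0.0438 and 0.04 without naive replicates 1, 2 and 5. For matrix remodelling it was 0.0375 with no filter, 0.0371 with library weights, 0.0408 rescaled to protein-coding genes, 0.0159 with the block, and 0.0156 and 0.027 without CCl4 replicate 2-4 and naive replicate 5. For glycolysis these 6 settings gave 0.0389, 0.0181, 0.0464, 0.045, 0.014 and 0.0245, and the transcript-level test 0.05. Interferon gamma genes were called with no filter (0.0215), quantile normalization (0.0398) and without CCl4 replicate 2-4 (0.0287), lipid uptake genes rescaled to protein-coding genes (0.046) and without CCl4 replicate 2-4 (0.0133), NRF2 genes with quantile normalization (0.0326) and without CCl4 replicate 1 (0.0414), and macrophage fusion genes with the block (0.0494). With an estimated correlation in the same settings none of these calls held, the lowest adjusted p being 0.558. Niche signalling genes (BMP, TGF-beta, Notch) had 5 of 20 higher and 9 lower, with Eng at -3.98 (5 and 10 adjusted over the list alone; camera adjusted p = 0.261, and 0.00787, lower, by fry). Eng, which endothelium also expresses, was highest among naive libraries in replicate 3 (809.1 TPM, with 793.1 in replicate 2) and lowest in replicate 5 (383.3 TPM). Clec4g had the same highest and lowest naive libraries, and all 17 endothelial markers fell. The source of Eng was not tested. For lipid uptake, storage and efflux 8 of 24 were higher and 3 lower (8 and 5 adjusted over the list alone; adjusted p = 0.107). Glycolysis had 6 of 18 higher and 1 lower (6 and 1; adjusted p = 0.0623), with Hk2 at 1.49. The NRF2 list had 1 of 19 higher and 8 lower (1 and 8; adjusted p = 0.0998), with Hmox1 at -1.19. For p53 targets 6 of 17 were higher and 5 lower (6 and 5; adjusted p = 0.764), with Gdf15 at 2.41 and Fas at -2.72. Endoplasmic reticulum stress genes had 3 of 19 higher and 3 lower (3 and 3; adjusted p = 0.884).

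All 6 erythroid genes tested fell (6 adjusted over the list alone; camera adjusted p = 0.00722, and adjusted p = 0.767 with an estimated correlation). Hba-a1, an alpha globin gene with a near-identical copy, stood at 1255 to 2294 TPM in naive libraries 1 to 4, at 61.2 in naive replicate 5 and at 15.1, 16.3 and 42.2 in CCl4 replicates 1, 2-4 and 3. Of 20 hepatocyte genes 16 fell (17 adjusted over the list alone; camera adjusted p = 0.000668, and adjusted p = 0.793 with an estimated correlation). Their summed TPM was 1648 in CCl4 replicate 1, within the naive range of 1423 to 2590, and 648 and 577.2 in CCl4 replicates 2-4 and 3 (exact permutation p = 0.107). Alb, serum albumin, averaged 509.0 ± 158 and 273.8 ± 230 TPM and did not pass by limma (adjusted p = 0.0561). It passed, lower, in 8 of 22 alternatives. CCl4 replicate 1 held 536.9 TPM of Alb, and replicates 2-4 and 3 held 171.6 and 112.8. Without 1 library its log2 fold change ranged from -1.81 to -0.69. Major urinary protein genes, male-biased products of hepatocytes in a family of near-identical copies whose reads may be split uncertainly, were among the largest falls. Mup15 averaged 149.2 ± 56.6 TPM in naive libraries and was listed at 0 in the 3 CCl4 libraries.

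NK cell and ILC1 genes had 0 of 13 called by limma over all genes or over the list alone (camera adjusted p = 0.725). Of 13 T cell genes 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.141); Lck, at -0.97, lost its call in 11 of 23 alternatives and was at -0.56 without CCl4 replicate 1. Of 11 B cell genes 2 fell (1 adjusted over the list alone; camera adjusted p = 0.251). CCl4 replicate 2-4 held the highest summed TPM of T, B and NK cell genes among the CCl4 libraries, and without it camera called all 3 lists lower (adjusted p = 0.0099, 0.00727 and 0.00727, with median log2 fold changes of -0.94, -0.87 and -0.59). With an estimated correlation and without that library the adjusted p was 0.567 for each of these lists. Plasma cell genes had 3 of 6 higher (3 adjusted over the list alone; camera adjusted p = 0.396), of which Jchain lost its call in 14 of 23 alternatives. Hepatic stellate cell and fibroblast genes had 5 of 18 higher, among them Col1a1, a fibrillar collagen chain, at 2.07, and 4 lower, among them Hgf at -1.52, which was not called at transcript level (5 and 4 adjusted over the list alone; camera adjusted p = 0.55). Of 8 cholangiocyte genes 1, Epcam, rose at 1.10 (camera adjusted p = 0.723). Neutrophil genes had 1 of 6 higher and 2 lower (camera adjusted p = 0.92), platelet genes 2 of 8 lower (0.807), and capsular and peritoneal macrophage genes 4 of 8 lower, with Icam2 at -2.72 (0.0593). The capsular macrophage list was called in the transcript-level test (0.0304) and without naive replicate 1 (0.0462) or 5 (0.04), with adjusted p of 0.611, 0.759 and 0.726 there with an estimated correlation, and fry called it lower (0.00162). Icam2, which endothelium also expresses, averaged 93.1 TPM of the 119.1 TPM summed over this list in naive libraries, and the endothelial markers fell too, with a median of -4.44. Adjusted over the list alone, these counts were 1 higher for cholangiocytes, 1 and 2 for neutrophils, 2 lower for platelets and 6 lower for capsular macrophages.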

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

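All tests of explanations in this part were chosen after the result was seen. In 16 of the 198 values examined over the 5 naive libraries (named genes, list sums and library measures), naive replicate 5 stood far from the other 4, with a gap to its nearest neighbour of most of the group's range. Naive replicate 2 stood apart in 2 more, which made 18. Chance flags about 1 in 20 groups, or 9.9 values here, and values of genes that move together are not independent.

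Naive replicate 5 was high in MHC class II genes, with gaps of 0.897 of the range for their summed TPM, 0.974 for H2-Eb1 and 0.956 for Ciita. It was high in genes of the monocyte and dendritic cell lists and in the lectin gene Mgl2, with 0.951 for Cd209a, 0.803 for Ccr2, 0.829 for Cx3cr1, 0.802 for Mgl2 and 0.864 for Wdfy4. The gaps were 0.911 for Pmaip1 and 0.76 for Pdgfb. Cd36 (0.714), Msr1 (0.721), Hes1 (0.805), Cxcl9 (0.793) and Ifi44 (0.75) also stood apart there, as did the share of Rn7sk in all TPM (0.788). In naive replicate 2 these were Ecm1 (0.731) and Pf4 (0.74).

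Naive replicate 5 lay between the other naive libraries and the CCl4 libraries in the first principal component. A label exchanged with a CCl4 library was argued against by its correlations, of which the lowest with a naive library exceeded the highest with a CCl4 library by 0.0554, and no CCl4 library lay among the naive ones. RNA of the CCl4 libraries mixed into it was argued against as the whole cause, since it needs 1 share for all genes that were higher in CCl4. Over 202 such genes, chosen without naive replicate 5, the median share was 16.6%, and 38.1% of the genes gave a range of shares that left this out, 49 above and 28 below, and the summed TPM of erythroid genes was 225 in this library against 3579 to 6755 in the other naive libraries, far lower than that share would leave. A separate isolation or library batch may also have set this library apart, and it stays open because the labels name no batch, as does a biological difference between mice, which was not tested.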

How the results depend on the processing

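The tests with added rescalings (without 7SL, 7SK, Rpph1 and Rmrp, or to protein-coding genes), and with an estimated correlation under other settings, were chosen after seeing the data. The count of called genes, 5906, ranged from 4578 to 7097 over the alternatives at gene level, and 4530 of the 5312 genes called with a replicate block were among the 5906. The replicate numbers 1 and 3 occur in both groups but the mice differ. Deviations from the group means correlated at 0.0772 for number 1 and -0.0414 for number 3, so the numbers did not pair the libraries. With the block the comparison rested on replicates 1 and 3 of each group, since each other number occurs in 1 library only, and 1 residual degree of freedom was left. Genes changed at least 2-fold came to 1799 with a pseudocount of 5. Quantile normalization gave 4011 higher genes and moved the median log2 fold change of all genes from -0.0642 to 0.105; 43.5% of its calls were lower, against 59.5%. Lists called numbered 14, but 0 with an estimated correlation (other cell types 0), and 14 to 22 over the libraries left out, with 22 without CCl4 replicate 2-4 (other cell types 4 to 7). Rescaling without haemoglobin, ribosomal RNA and hepatocyte genes left 2 other cell type lists, since it removes those genes. With an estimated correlation under the other settings 0 lists were called, except 1, ribosomal proteins, with either added rescaling (adjusted p = 0.0138 and 0.0134). The estimated correlation changes the test and not the medians, and these lists lost their call under it: Kupffer cell identity -2.69, endothelium -4.44, erythroid -4.95, hepatocyte -1.43, uptake -1.37, complement -1.35, monocyte 1.66, MHC class II 2.11, immediate early 1.01, histone 0.95, cell cycle 0.82, scar-associated 0.81, ribosomal protein 0.63, lysosome 0.53 (0.53 without a call under fry too). Without a call, scar-associated genes had medians of 0.86 with median-of-ratios and 0.90 with quantile scaling, and lysosome genes 0.61 and 0.36. Over the libraries left out scar-associated genes ranged from 0.45 (without CCl4 replicate 1) to 1.08, and lysosome genes ranged from 0.17 (without CCl4 replicate 1) to 0.72 without 1 library. The share of the first component was 63.2% with a pseudocount of 0.1, 77.2% with 5, 68.2% without a filter or without 7SL and the like, 77.8% with the strict filter, 75.7% with protein-coding genes, and 69.6% to 77.7% without 1 library. Apart from the medians without 1 library given above, some medians moved by over 1.5 times with their call kept. These were erythroid genes with no filter (-2.56), cell cycle genes with a pseudocount of 5 (0.51), and, with the block, complement (-0.88) and lysosome (0.82) genes. Of the 35 lists not called, 15 were called under some alternative, 4 of them by fry alone (LXR target, niche signalling, inflammatory and apoptotic cell clearance genes) and 11 by camera. Fry also called interferon gamma and capsular macrophage genes. By camera the glycolysis, macrophage core and matrix lists were called with no filter, library weights, the block or rescaling to protein-coding genes, and without CCl4 replicate 2-4 or naive replicate 5. Also called were macrophage core with protein-coding genes only or without naive replicate 1 or 2, interferon gamma with no filter or quantile normalization, lipid uptake rescaled to protein-coding genes, NRF2 with quantile normalization or without CCl4 replicate 1, glycolysis and capsular macrophage at transcript level, capsular macrophage without naive replicate 1 or 5, macrophage fusion with the block, and the B, T and NK cell, interferon gamma and lipid uptake lists without CCl4 replicate 2-4. In total 18 lists were called after rescaling to protein-coding genes. Of 119 called named genes 17 lost the call under some alternative: Bub1, Csf3r, Cxcr4, Ecm1, Hgf, Me1, Slc16a3, Tfeb and Tpx2 at transcript level, Hmox1, Pfkfb3 and Txn1 with the block, Cd9 without CCl4 replicate 1, Trib3 without CCl4 replicate 2-4 or 3, Asns with quantile normalization or without CCl4 replicate 3, and Lck and Jchain under many. Named genes that were not called gained a call, with the same sign, in 39 gene and setting pairs. Alb gained it in 8 settings, and Cd226 and Csf1r in 5 each. Sign reversed in 8 named genes. Of those 8, Tfeb alone was called: it went to -0.62 at transcript level, where Spp1 was at -0.98 and Cd79b at 0.0260. With quantile normalization Id3 was at -0.0689 and Ccl5 at 0.0139, and with the block Adgre1 was at 0.42. Without 1 library the uncalled genes Adgre1 (-0.67 to 0.22), Ccl5 (-0.59 to 0.21), Cd79b (-0.45 to 0.0379), Id3 (-0.0871 to 0.21), Pf4 (-0.19 to 1.07) and Tstd1 (-0.61 to 0.17) changed sign. Causes were not tested. TPM keep no depth, so what depth limits is unknown.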

Other observations

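Some gene families moved with the groups. Of 82 genes of cytosolic ribosomal proteins 60 rose and 1 fell (67 and 1 adjusted over the list alone), with a median log2 fold change of 0.63 (camera adjusted p = 2.25e-14, and adjusted p = 0.64 with an estimated correlation, or 0.0134 when TPM were also rescaled to protein-coding genes). Histone genes, many of which lack poly(A) tails and belong to families with near-identical copies, rose in 48 of 76 cases and fell in 1 (54 and 1 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 2.66e-14, and adjusted p = 0.64 with an estimated correlation). Both medians stayed above 0 under each of the 5 rescalings run. The remaining families were not called by camera. Of 36 complex I subunit genes 1 rose and 3 fell, of 44 subunits of complexes II to V 2 rose and 2 fell, of 74 mitochondrial ribosomal protein genes 1 rose and 5 fell, and of 39 proteasome genes 1 rose and 2 fell. Cathepsins had 4 of 13 higher and 3 lower, V-ATPase subunits 1 of 19 higher, collagens 4 of 23 higher and 5 lower, chemokines 8 of 27 higher and 5 lower, and C-type lectins 9 of 25 higher and 8 lower. Adjusted over the list alone, the counts higher and lower were 1 and 1, 1 and 0, 0 and 1, and 0 and 0 for the first 4 of these families, and 4 and 4, 1 and 0, 4 and 7, 9 and 5, and 10 and 8 for the others. Summed TPM of collagens fell from 724.8 ± 196 in naive to 242.3 ± 10 in CCl4 libraries. Such a sum is weighted to the most abundant genes: the median log2 fold change of the collagens was 0.13, and single genes ranged from -4.12 to 2.07. Which cells the collagen transcripts came from was not tested. Summed TPM of C-type lectins fell from 4834 ± 813 to 1151 ± 118, and that of chemokines rose from 735.6 ± 65.3 to 1109 ± 64.3. Most of the naive C-type lectin sum was the endothelial gene Clec4g and the Kupffer cell gene Clec4f. These averaged 2289 and 1397 TPM in naive and 89.0 and 77.7 TPM in CCl4 libraries, so that fall is not one of the family as a whole. For each of the sums of collagens, C-type lectins and chemokines the exact permutation p was 0.0357, two-sided, and 0.094 adjusted over the lists. In 13 lists the median, the mean and the direction of camera differed in sign, and 0 of these were called (the type I interferon, alternative activation, p53, endoplasmic reticulum stress, cholangiocyte, neutrophil, complexes II to V, mitochondrial ribosomal protein, cathepsin, V-ATPase, collagen, chemokine and C-type lectin lists).

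The tests in this paragraph were chosen after the result was seen. Kupffer cell identity and sinusoidal endothelium genes fell together, and the lists share 1 gene, Cdh5; 3 of the 17 endothelial and 14 of the 25 Kupffer cell genes are on some other list. Scaling set by 7SL and 7SK RNAs was argued against, since after rescaling to protein-coding genes the medians were -2.84 for the Kupffer cell list and -4.52 for the endothelial list. A lower share of Kupffer cells alone would raise the other cell types alike, and these moved apart, from a median of 1.66 for monocytes to -4.95 for erythroid genes, a difference of 6.62 (1.24 and -2.56 with no filter, still on opposite sides of 0). Fewer sinusoidal endothelial cells, or less of their RNA, in the CCl4 preparations may account for the endothelial part and stays open: the log2 fold changes ranged from -5.07 to -2.59, with an SD of 1.92 times their median standard error of 0.293, just inside a limit of 2 chosen after the values were seen, so 1 common factor is not shown. For the Kupffer cell genes that SD was 5.13 times, and whether these cells lost the transcripts or were replaced by monocyte-derived cells stays open in bulk RNA, as does a sort or gate that differed between groups.

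Other splits of the libraries were compared with the real one, as planned before the data were examined. Of the 56 splits of 8 libraries into 5 and 3, only the real one gave as many called genes (5906, against at most 2). It alone also gave as many genes changed at least 2-fold (3182, with 2 as the highest of the others). A rank of 1 in 56 is the best this design allows. Every other split mixes the groups, which puts the group difference into its spread, so few calls there were built in. The splits therefore cannot exclude chance, nor a difference in preparation between the groups. The number of lists called by camera did not set the real split apart: 37 splits gave 14 lists or more, and the highest of the others gave 26. The other splits hold part of the group difference, so for lists too they do not measure chance, in total or list by list. Counted list by list after seeing this, the splits with as small a p, the real one included, were 1 of 56 for the endothelial list, 3 for Kupffer cell identity, 4 for monocytes, 7 for MHC class II and for uptake receptors, 8 for scar-associated macrophages and for ribosomal proteins, 9 for erythroid, 10 for immediate early, 12 for histone, 14 for cell cycle and for complement, 19 for hepatocyte and 26 for lysosome genes.

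Of 6236 unmatched transcripts that passed the TPM filter, limma called 894, of which 364 were higher and 530 lower.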
